A study of Homo sapiens with 6 samples.

How the data were processed

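Total RNA of IMR90 cells was converted to biotin-labelled RNA and hybridised to Illumina BeadChip arrays, per the labels' protocols. The 6 samples formed 3 groups of 2 arrays (untreated, GFP retrovirus and OSKM retroviruses, all at day 5), taken from the sample descriptions, which call the arrays technical replicates 1 and 2. The deposited signal table holds, per the file headers, the average bead signal of each probe, an intensity on a linear scale that had not been normalized, for 47323 probes. Beside it stands a detection p-value per probe and array, which per the file headers tests the probe's signal and in these values runs in steps of 1 in 770. GenomeStudio is named in the submitters' processing notes, and its version and background setting are not given in the sources used here. The authors' processed table holds intensities of 47231 of these probes on a linear scale, with a median of 58 on each array and nearly equal quantiles, so it had been normalized between arrays, by a method not given in the sources used here. Its values are not centred. In it the columns of the 2 untreated arrays are exchanged against the signal table (rank correlation 1 with the other untreated array and 0.9452 with its own). This affects the replicate number of the untreated arrays and no group.

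Probes were named from the platform annotation: 30121 of the probes were listed with a gene, 30113 of them with 1 gene and 8 with several, and 17202 were not listed, which leaves them unnamed here. Of the named probes, 30074 were matched by gene identifier to a RefSeq gene table and 0 names needed an update. Background correction and normalization used the steps of limma's neqc. Background was estimated from the detection p-values, an offset of 16 was added, quantile normalization was applied on the linear scale, and log2 was taken last. A probe was taken as detected at a detection p under 0.01 on both arrays of at least 1 group, which held for 16956 probes. Each gene was read by its detected probe with the highest mean over all 6 arrays, which gave 10552 genes. Of these genes 2644 had at least 2 detected probes, and probes of 1 gene were called in opposite directions for 12 genes in OSKM against GFP, 57 in OSKM against untreated and 53 in GFP against untreated.

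Genes were tested with limma (lmFit and eBayes) in 1 fit over all 6 arrays with 3 residual degrees of freedom (prior degrees of freedom 9.45), and called at a Benjamini-Hochberg adjusted p under 0.05. Since technical replicates spread little, each count is given again for genes that differ at least 2-fold. The comparisons were OSKM with GFP, OSKM with untreated, GFP with untreated, and OSKM with the mean of both controls. In all, 32 gene lists were fixed before the data were examined, as were the gene tests, the list tests of OSKM with GFP and GFP with untreated, their alternatives and the rule for naming genes. The list test of OSKM with untreated and most tests of explanations were chosen after the data were seen. Those with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation, for which camera uses the 3 residual degrees of freedom of the arrays. Named genes were the 8 highest and 8 lowest called changes of each comparison without overlap between arrays of the groups, all estrogen-related receptor and delivered genes, up to 4 members of every other list by size of change in OSKM against GFP, and IDH3A, NDUFA2, ATP5MC1, CYCS, SOD2, NOX4 and CAT. CD24 was also read by probe after its values had been seen. Correlations and covariances of changes between comparisons that share arrays were set against 20 simulations of unchanged groups. The other detected probes of the named genes were read after the data had been seen, and the text gives each that was not called, or was called the other way, where the probe used was called. Some that were called the same way but changed less are given too.

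Alternatives were other background corrections (none, normexp with an offset of 50, neqc with an offset of 1), median scaling or cyclic loess in place of quantile normalization, the authors' processed values, other filters on dim probes, the mean of probes or every probe on its own, eBayes with trend and robust settings, fits of only the groups compared, the replicate number as a block, leaving out each array, and a fit on culture means. The code was tested on simulated data of the OSKM and GFP comparison with 10552 genes, where it recovered 58.2% of genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2, with 12 false calls. With 2 arrays per group, the number of arrays limits the precision, and the median SE of a change between 2 groups was 0.125. No genome was used, so no coordinates are given. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.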

Results

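Gene expression was measured in IMR90 cells, human fibroblasts from embryonic lung, at day 5 of a reprogramming experiment. The cells fell into 3 groups: untreated cells, cells infected with a retrovirus carrying GFP, a fluorescent protein that serves as a control for infection, and cells infected with retroviruses carrying OSKM, the reprogramming factors Oct4, Sox2, Klf4 and c-Myc (genes POU5F1, SOX2, KLF4 and MYC). Together these factors can turn somatic cells into induced pluripotent stem cells. By its title the series concerns the estrogen-related receptors alpha and gamma (ESRRA and ESRRG), orphan nuclear receptors that control genes of mitochondrial metabolism, in the reprogramming of somatic cells.

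RNA of each group was read on 2 Illumina BeadChip arrays, on which each probe is carried by many beads and the brightness of bound, biotin-labelled RNA is averaged. The median signal of the 47323 probes ranged from 54.2 to 60.3 over the 6 arrays, and between 15114 probes (31.9%, an untreated array) and 16739 probes (35.4%, an OSKM array) were detected on an array at a detection p under 0.01. Over the 10552 genes tested, arrays of the same group correlated at r = 0.9933 (untreated), 0.9952 (GFP) and 0.995 (OSKM). Between groups r lay between 0.9528 and 0.9533 for GFP and OSKM, between 0.923 and 0.9258 for untreated and OSKM, and between 0.9057 and 0.9082 for untreated and GFP. These are correlations across genes, which are not independent replicates. The labels call the 2 arrays of a group technical replicates. Apart from the fit on culture means, the p-values of genes therefore measure only the spread between arrays of 1 culture per group. Camera with the preset correlation sets the genes of a list against all other genes, so its p-values rest on spread between genes. No p-value here measures the spread between cultures of a group. Below, levels are normalized log2 intensities given as mean ± SD (n = 2 arrays), changes are log2 fold changes ± SE from limma, and adjusted p is limma's, by the Benjamini-Hochberg method. Where a gene was not above background on either array of a group, its fold is a bound: the mean of the brighter group was set against the higher of the dim probe's own level and the lowest level of a detected probe, array by array. The bound is that of the probe used, and other probes of a gene could change less.

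The comparison of OSKM with GFP sets cells given the 4 factors against a control for infection. It also holds any other difference between these cultures and their viruses, so its changes cannot be assigned to the factors alone. OSKM cells had higher levels of genes of DNA replication and mitosis, of ribosome assembly and of secreted inflammatory proteins, and lower levels of contractile genes. The DNA replication, mitosis and ribosome assembly lists were lower in GFP than in untreated cells. Against untreated cells their medians in OSKM were -1.37, -1.09 and 0.04. The calls of OSKM against GFP for the lists named here were made with a preset correlation between genes. They were lost with an estimated one (adjusted p = 0.068 for contractile genes and 0.0578 for the others). SULF1, an enzyme that removes sulfate groups from heparan sulfate outside the cell, rose from 5.86 ± 0.16 to 12.47 ± 0.05 (change 6.60 ± 0.13, adjusted p = 2.96e-12). H19, an imprinted noncoding RNA, was at least 47.4-fold higher in OSKM, CD24, a surface glycoprotein, at least 33.3-fold, and PODXL, a surface sialomucin abundant on pluripotent stem cells, at least 19.6-fold. The largest falls were in NNAT, an imprinted gene of neural tissue (-2.92 ± 0.14), and in MERTK, a receptor tyrosine kinase (-2.76 ± 0.12).

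In all, 4202 of 10552 genes passed an adjusted p of 0.05 in limma, 2092 higher and 2110 lower in OSKM, and 743 of them differed at least 2-fold, 487 higher and 256 lower. That 2-fold count fell to 352 with normexp and an offset of 50, 455 with no background correction, 461 with the authors' values and 470 among genes detected on all 6 arrays. The other genes with the largest rises were STMN2, a tubulin-binding protein of neurons (at least 23.8-fold), PI16, a peptidase inhibitor (at least 17.2-fold), DKK1, a secreted Wnt antagonist (4.54 ± 0.13), and SLC8A2, a sodium-calcium exchanger (at least 9.74-fold). The other largest falls were in MSX2, a homeobox factor (at least 4.16-fold lower in OSKM), FRZB, a secreted Wnt antagonist (-2.45 ± 0.13), C1QL1 (-2.44 ± 0.14, detected on 1 of the 2 OSKM arrays), TMOD1, which caps actin filaments (-2.43 ± 0.12), SNCAIP, a synuclein-binding protein (-2.29 ± 0.11), and CNN1, the smooth muscle calponin (at least 3.74-fold lower). CD24 had another detected probe, which rose by 1.37 ± 0.11. Other detected probes of PODXL and MERTK also moved less than the probes used, by 2.36 ± 0.16 and -1.39 ± 0.13.

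The probes of the delivered genes gave differing results. POU5F1 was not above background in untreated (4.38 ± 0.03) or GFP cells (4.40 ± 0.04) and reached 8.56 ± 0.04 in OSKM, at least 9.83-fold above GFP (limma adjusted p = 6.4e-11), while its other probe was not above background in any group. The brighter MYC probe rose from 9.49 ± 0.03 to 10.94 ± 0.01 (1.45 ± 0.12, adjusted p = 9.5e-07) and the other MYC probe fell from 8.26 ± 0.09 to 6.82 ± 0.06 (-1.43 ± 0.12). With the MYC probes averaged, the change was 0.009 and no longer called (adjusted p = 0.953). KLF4 did not pass the test (6.68 ± 0.10 in GFP, 6.45 ± 0.02 in OSKM, adjusted p = 0.142), and SOX2 was not above background on any array. Of the 3 delivered genes tested, 2 rose, also when adjusted over the list alone, but POU5F1 was tested only because it was detected in OSKM. The list passed limma's camera test (adjusted p = 0.0301, but adjusted p = 0.196 with an estimated correlation) and lost the call with the probes of a gene averaged (adjusted p = 0.246), with a background offset of 1 (0.0512) or with no filter on dim probes (0.0766). Where the probes lie on the transcripts is not given in the sources used here, so it is open which of them read the delivered sequences. Nor do these values show whether KLF4 and SOX2 were expressed from the retroviruses.

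Genes of cell division were higher in OSKM than in GFP cells. Of 25 DNA replication genes, 22 rose and 3 did not pass, with the same counts when adjusted over the list alone. CDC45, which loads onto replication origins with the helicase, rose by 2.11 ± 0.14, and GINS2, another part of that helicase, by 1.62 ± 0.13. MCM2, a subunit of its ring, rose by 1.36 ± 0.13 and was detected on 1 of the 2 GFP arrays. Of 28 mitosis genes, 26 rose, also when adjusted over the list alone, among them the kinase AURKB (1.64 ± 0.11), cyclin CCNA2 (1.58 ± 0.12) and the ubiquitin-conjugating enzyme UBE2C (1.30 ± 0.11). The median change was 0.94 in both lists. Camera gave an adjusted p of 4.18e-11 for DNA replication and of 2.28e-13 for mitosis, and for each of them adjusted p = 0.0578 with an estimated correlation. Both lists were lower in GFP than in untreated cells, by a median of -2.18 for DNA replication and -2.03 for mitosis. Their OSKM medians lay between those of the control groups. Among p53 targets and cell cycle inhibitors, 3 of 20 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.827). The inhibitor CDKN1C fell by 1.81 ± 0.13, and CDKN2A, which encodes the inhibitor p16, rose by 0.74 ± 0.14.

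Of 24 MYC targets in ribosome biogenesis, 22 rose and 1 fell, also when adjusted over the list alone. The median change was 0.68 (adjusted p = 1.07e-08; adjusted p = 0.0578 with an estimated correlation). NOP16, a nucleolar protein, rose by 1.24 ± 0.12, the nucleolar phosphoprotein NOLC1 by 1.21 ± 0.13, RRP12 by 0.98 ± 0.13 and the nucleoside diphosphate kinase NME1 by 0.95 ± 0.12. Cytosolic ribosomal proteins did not move together: 9 of 69 rose and 3 fell (9 and 2 when adjusted over the list alone, adjusted p = 0.613), with RPL36A highest at 1.74 ± 0.13. Amino acid and unfolded protein stress genes rose in 12 of 18 and fell in 1 (13 and 1 when adjusted over the list alone), with a median of 0.53 (adjusted p = 1.34e-05; adjusted p = 0.0737 with an estimated correlation). Examples were the amino acid transporter SLC7A5 (1.94 ± 0.11), the mitochondrial folate enzyme MTHFD2 (1.66 ± 0.12) and the pseudokinase TRIB3 (1.12 ± 0.14). Against untreated cells the median of the MYC targets was 0.04 in OSKM and -0.63 in GFP. That of the stress genes was -0.94 in OSKM and -1.4 in GFP.

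Secreted inflammatory genes rose in 15 of 18 and fell in 1, also when adjusted over the list alone, with a median of 1.39 (adjusted p = 6.97e-10; adjusted p = 0.0578 with an estimated correlation). The cytokine IL6 rose by 3.90 ± 0.15, from 6.14 ± 0.20 to 10.04 ± 0.07, and the chemokines CXCL6 and CXCL8 rose by 3.03 ± 0.15 and 2.54 ± 0.12. CCL20, another chemokine, rose from 5.87 ± 0.03 to 8.87 ± 0.17. Interferon response genes rose in 14 of 25 and fell in 0 (14 and 1 when adjusted over the list alone; adjusted p = 0.000149; adjusted p = 0.0822 with an estimated correlation). MX1, an antiviral GTPase, rose by 2.41 ± 0.19, and IFI27, an interferon-induced mitochondrial protein, was at least 4.29-fold higher in OSKM.

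The estrogen-related receptors and their coregulators moved apart. ESRRA rose from 6.59 ± 0.22 in GFP to 7.43 ± 0.08 in OSKM (0.83 ± 0.13, adjusted p = 0.000251). ESRRG fell from 6.57 ± 0.03 to 5.36 ± 0.03 (-1.21 ± 0.12, adjusted p = 5.44e-06), read by 1 of its 3 probes, the others being not above background. The coactivator PPARGC1A (PGC-1alpha) fell by 0.61 ± 0.14 (adjusted p = 0.00368), a call that rested on OSKM replicate 2 (adjusted p = 0.0523 without it), and PPRC1, a related coactivator, rose by 0.52 ± 0.11. The corepressor NRIP1 did not pass (-0.34 ± 0.14, adjusted p = 0.0608) but did under 8 of the other settings, with an adjusted p between 0.0293 and 0.0476 there. ESRRB and PPARGC1B were not above background on any array. Of the 5 genes tested, 2 rose and 2 fell (2 and 3 when adjusted over the list alone, adjusted p = 0.688).

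**Figure D1:**
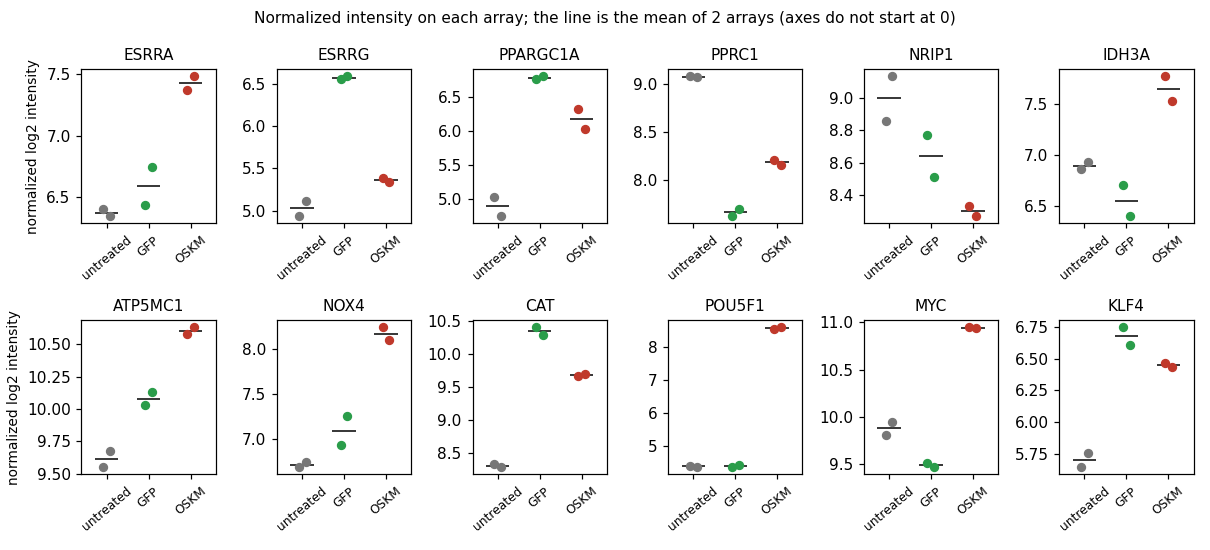
Normalized log2 intensity (vertical axes, which do not start at 0) of 12 genes on each of the 6 arrays, by group, with a line at the mean of 2 arrays. ESRRA lay highest in OSKM (7.43), while ESRRG and PPARGC1A lay highest in GFP (6.57 and 6.79).

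Respiratory chain genes as groups did not pass in OSKM against GFP. Complex I had 3 of 33 genes higher and 2 lower (1 and 1 when adjusted over the list alone, adjusted p = 0.624). Complexes II to IV with cytochrome c had 3 of 22 higher (3 when adjusted over the list alone, adjusted p = 0.622). ATP synthase had 2 of 16 higher and 1 lower (1 and 0 when adjusted over the list alone, adjusted p = 0.846). Single members moved: the ATP synthase subunit ATP5MC1 rose by 0.52 ± 0.12, and the complex I subunit NDUFA6 fell by 0.75 ± 0.14. SDHA of complex II rose by 0.50 ± 0.13, a call lost without GFP replicate 2 (adjusted p = 0.0987) or OSKM replicate 1 (adjusted p = 0.0618). Neither NDUFA2 (-0.14 ± 0.13, adjusted p = 0.421) nor cytochrome c, CYCS (-0.15 ± 0.15, adjusted p = 0.439), passed. Pyruvate oxidation and the citrate cycle had 5 of 17 genes higher and 2 lower (6 and 2 when adjusted over the list alone, adjusted p = 0.192). There IDH3A, the catalytic subunit of mitochondrial isocitrate dehydrogenase, rose by 1.10 ± 0.14 (adjusted p = 4.26e-05), and OGDH, of the oxoglutarate dehydrogenase complex, by 0.67 ± 0.12. Fatty acid oxidation had 2 of 18 higher and 4 lower, also when adjusted over the list alone (adjusted p = 0.622), with CPT1B, which carries fatty acids into mitochondria in muscle, at least 1.16-fold lower.

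Glycolysis genes rose in 11 of 20 and fell in 0, also when adjusted over the list alone, with a median of 0.39 (adjusted p = 0.00162; adjusted p = 0.151 with an estimated correlation). Against untreated cells their median was -0.15 in OSKM and -0.52 in GFP. Over GFP, hexokinase HK2 rose by 1.78 ± 0.12, phosphofructokinase PFKP by 1.40 ± 0.12 and enolase ENO1 by 0.67 ± 0.13. The other detected HK2 probe rose by 0.65 ± 0.20. Mitochondrial biogenesis genes rose in 6 of 16, also when adjusted over the list alone (adjusted p = 0.0132; adjusted p = 0.151 with an estimated correlation), with the mitochondrial ribosomal RNA methyltransferase TFB1M at 1.36 ± 0.13 and the mitochondrial transcription factor TFAM at 0.95 ± 0.12. Against untreated cells the median of this list was 0.04 in OSKM and -0.36 in GFP. In OSKM against GFP, mitochondrial ribosomal proteins rose in 15 of 76 (6 when adjusted over the list alone) by a small median of 0.11 (adjusted p = 0.0434, but adjusted p = 0.151 with an estimated correlation). Over all genes tested a like share rose (2092 of 10552), while 2110 fell, against 0 in this list. The call was also lost without GFP replicate 1, GFP replicate 2 or OSKM replicate 1 (adjusted p = 0.0617, 0.0603 and 0.102) and with median scaling or cyclic loess (adjusted p = 0.192 and 0.069). Antioxidant and oxidase genes went both ways, 8 of 24 higher and 7 lower (9 and 8 when adjusted over the list alone, adjusted p = 0.833). The mitochondrial carrier UCP2 rose by 1.47 ± 0.12 and the hydrogen peroxide source NOX4 by 1.09 ± 0.13, while catalase, CAT, fell by 0.66 ± 0.11. The other detected NOX4 probe rose by 0.44 ± 0.12. Superoxide dismutase SOD2 passed narrowly (0.34 ± 0.12, adjusted p = 0.0388) and lost the call when any GFP or OSKM array was left out (adjusted p from 0.0824 to 0.187) and with median scaling or cyclic loess (adjusted p = 0.325 and 0.0804) or a background offset of 1 (0.0638). Its other detected probe, which is dimmer, rose by 0.59 ± 0.12 (adjusted p = 0.00214).

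Contractile genes were lower in OSKM: 11 of 12 fell (12 when adjusted over the list alone), with a median of -0.84 (adjusted p = 7.06e-07; adjusted p = 0.068 with an estimated correlation). The myosin kinase MYLK fell by 1.33 ± 0.11, and the smooth muscle actin ACTG2 and TGFB1I1, a focal adhesion protein, by 1.20 ± 0.11 and 1.20 ± 0.12. Fibroblast matrix and surface genes rose in 10 of 23 and fell in 4, also when adjusted over the list alone (adjusted p = 0.0286; adjusted p = 0.166 with an estimated correlation), a call also lost with median scaling (adjusted p = 0.0767) and cyclic loess (adjusted p = 0.0525). The surface protein THY1 rose by 1.85 ± 0.12 and collagen COL1A1 by 1.10 ± 0.12. Against untreated cells the median of the matrix and surface list was -0.12 in OSKM and -0.57 in GFP. Over GFP, mesenchymal regulators rose in 2 of 13 and fell in 8, also when adjusted over the list alone (adjusted p = 0.0982). N-cadherin, CDH2, rose by 2.33 ± 0.12, whereas the transcription factor SNAI2 fell by 1.88 ± 0.13, TGFB2 by 0.92 ± 0.14 and fibronectin, FN1, by 0.79 ± 0.13, with 1 of its 2 other detected probes at -0.84 ± 0.14 and the other not past (-0.24 ± 0.15, adjusted p = 0.245). Epithelial genes rose in 4 of 11 and fell in 1 (5 and 1 when adjusted over the list alone, adjusted p = 0.192). The tight junction gene CLDN7 was at least 1.94-fold higher in OSKM, the epithelial factor ELF3 rose by 1.00 ± 0.14, and plakoglobin, JUP, fell by 1.13 ± 0.12.

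Of 23 pluripotency genes with a probe, 5 were tested, and 4 of these rose, also when adjusted over the list alone (adjusted p = 0.00032; adjusted p = 0.104 with an estimated correlation). Besides PODXL, L1TD1, an RNA-binding protein of embryonic stem cells, was at least 3.90-fold higher in OSKM and DPPA4 at least 3.18-fold. The other of the 4, the phosphatase ALPL, was not above background in GFP (4.46 ± 0.06) or OSKM cells (4.98 ± 0.09), so no fold is given, and it was highest in untreated cells (7.59 ± 0.10). L1TD1 and DPPA4 were not above background in untreated or GFP cells and were tested only because they were detected in OSKM. The filter thus fixed their direction. Pluripotency genes not detected on both arrays of any group lie outside the count of 5. Across the 30 lists that could be tested, 13 passed camera with the preset correlation, 12 higher and 1 lower in OSKM, and with an estimated correlation 0 did, the lowest adjusted p being 0.0578. For the cytosolic ribosomal and reference gene lists, the median, the mean and the test differed in sign.

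**Figure D2:**
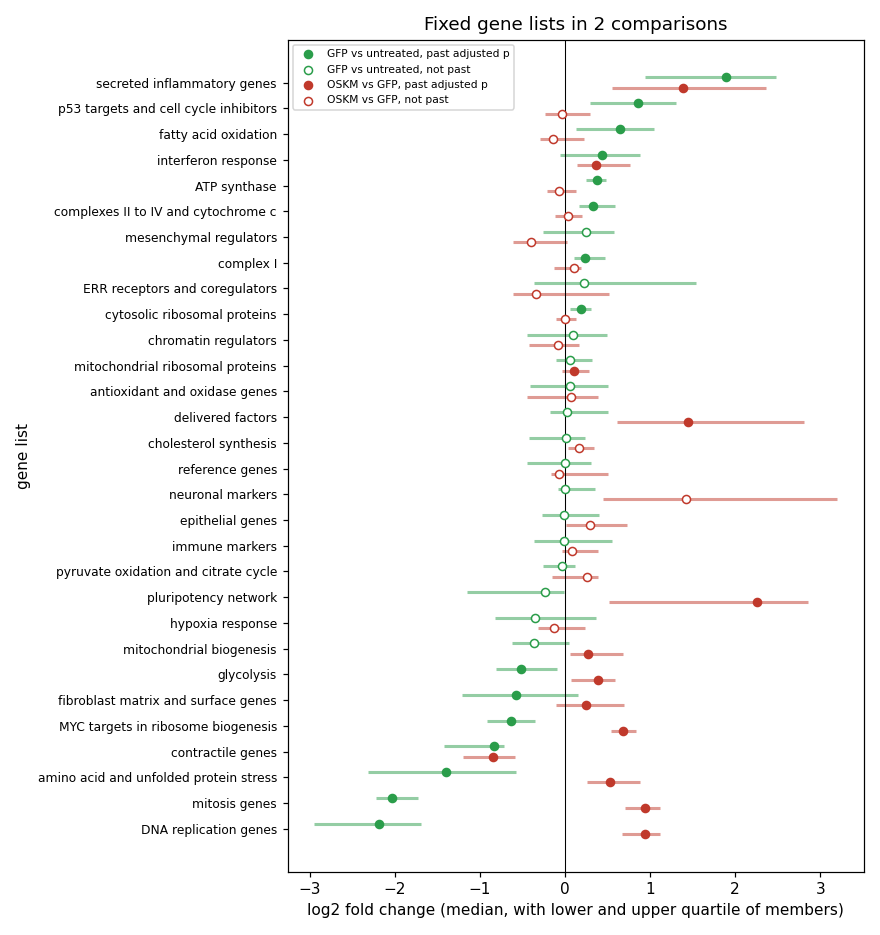
Median log2 fold change (horizontal axis, with a bar from the lower to the upper quartile of members) of the 30 tested gene lists in GFP against untreated and OSKM against GFP, with filled points for lists past an adjusted p of 0.05 with the preset correlation. DNA replication genes had a median of -2.18 in GFP against untreated and 0.94 in OSKM against GFP.

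The comparison of GFP with untreated cells sets an infected culture against an uninfected one, so it holds the effect of infection together with any other difference between these 2 cultures. GFP cells had far lower levels of cell division genes, lower contractile, matrix, glycolysis and amino acid stress genes, and higher inflammatory and p53 target genes. Of these list calls those of cell division genes held with an estimated correlation, and the others were lost (adjusted p from 0.0705 to 0.158). KYNU, an enzyme of tryptophan breakdown, was at least 97.5-fold higher in GFP, and PDK4, a kinase that inhibits pyruvate dehydrogenase, at least 50.2-fold. The other detected KYNU probe rose by 5.42 ± 0.11. ANO1, a calcium-activated chloride channel, was at least 29.3-fold lower, and TNFRSF12A, the TWEAK receptor, fell by 4.16 ± 0.12. In limma 6058 of 10552 genes passed, 3136 higher and 2922 lower in GFP, and 1657 differed at least 2-fold, 812 higher and 845 lower (965 in all with normexp and an offset of 50).

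Other large rises in GFP were in C11orf96 (6.09 ± 0.13), ANGPTL4, an inhibitor of lipoprotein lipase (5.51 ± 0.12), the prostaglandin synthase PTGS2 (5.20 ± 0.13), the nuclear receptor NR4A2 (4.80 ± 0.13, detected on 1 of the 2 untreated arrays), BMP5 (at least 17.1-fold) and the protease inhibitor TFPI2 (4.61 ± 0.11). Other detected probes of ANGPTL4 rose less, by 1.19 ± 0.15 and 2.04 ± 0.15. Other large falls were in the carboxypeptidase CPA4 (at least 15.5-fold lower in GFP), the scavenger receptor OLR1 (at least 12.6-fold lower), the matricellular protein CCN1 (-4.08 ± 0.13), GFRA1, a receptor for GDNF (at least 14.3-fold lower), MARCHF4 (at least 8.97-fold lower) and PSG4 (-3.99 ± 0.12). SULF1 and DKK1, which rose in OSKM against GFP, fell here by 3.32 ± 0.13 and 3.51 ± 0.13, whereas H19, CD24 and PI16, which also rose there, were not above background in either control.

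Of 25 DNA replication genes, 24 fell in GFP against untreated, and of 28 mitosis genes, 27 fell, with the same counts when adjusted over the list alone. Camera gave adjusted p = 1.58e-15 and 5.53e-17, and both calls held with an estimated correlation (adjusted p = 0.0401 for each). CDC45 fell by 3.71 ± 0.14 and AURKB by 3.02 ± 0.11. Among p53 targets and cell cycle inhibitors, 14 of 20 rose (14 higher and 1 lower when adjusted over the list alone; adjusted p = 0.000183; adjusted p = 0.0896 with an estimated correlation), with CDKN1C at 1.99 ± 0.13 and the p53-induced oxidoreductase TP53I3 at 1.79 ± 0.12. MYC targets in ribosome biogenesis fell in 18 of 24 (19 when adjusted over the list alone; adjusted p = 4.18e-05; adjusted p = 0.0896 with an estimated correlation). Amino acid and unfolded protein stress genes fell in 16 of 18 and rose in 2, also when adjusted over the list alone (adjusted p = 7.54e-07; adjusted p = 0.0778 with an estimated correlation), with SLC7A5 at -3.90 ± 0.11.

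Secreted inflammatory genes rose in 17 of 18, also when adjusted over the list alone (adjusted p = 1.02e-08; adjusted p = 0.0705 with an estimated correlation). CXCL8 rose by 3.93 ± 0.12, and the exception, IL6, fell by 1.82 ± 0.15. Interferon response genes rose in 14 of 25 and fell in 2, also when adjusted over the list alone (adjusted p = 0.0136; adjusted p = 0.158 with an estimated correlation). Contractile genes fell in 12 of 12, also when adjusted over the list alone (adjusted p = 1.03e-05; adjusted p = 0.0896 with an estimated correlation), with TAGLN, an actin-binding protein of smooth muscle, at -2.58 ± 0.13. Matrix and surface genes fell in 12 of 23 and rose in 5, also when adjusted over the list alone (adjusted p = 0.0357; adjusted p = 0.158 with an estimated correlation), a call lost without untreated replicate 2 (adjusted p = 0.0528). The collagen cross-linking enzyme LOX fell by 2.76 ± 0.13.

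Among metabolic lists, glycolysis genes fell in 14 of 20 and rose in 3, also when adjusted over the list alone (adjusted p = 0.00523, but adjusted p = 0.158 with an estimated correlation). HK2 was at -1.99 ± 0.12, with its other detected probe at -0.55 ± 0.20, and PFKP at -1.86 ± 0.12. Fatty acid oxidation genes rose in 11 of 18 and fell in 2, also when adjusted over the list alone (adjusted p = 0.00433; adjusted p = 0.146 with an estimated correlation). Complex I genes rose in 12 of 33 (11 when adjusted over the list alone; adjusted p = 0.024). Complexes II to IV with cytochrome c rose in 12 of 22 and fell in 2 (13 and 2 when adjusted over the list alone; adjusted p = 0.0365). ATP synthase genes rose in 8 of 16 and fell in 1 (9 and 1 when adjusted over the list alone; adjusted p = 0.0357). For each of these 3 lists adjusted p = 0.158 with an estimated correlation, and each lost its call with median scaling (adjusted p = 0.0508, 0.064 and 0.0729). The list of complexes II to IV also lost it without untreated replicate 1 or GFP replicate 1 (adjusted p = 0.0602 and 0.0518). Cytosolic ribosomal proteins rose in 19 of 69 and fell in 4 (14 and 2 when adjusted over the list alone, adjusted p = 0.0497, but adjusted p = 0.158 with an estimated correlation). Over all 10552 genes tested a like share rose (3136) and a larger share fell (2922). The call was also lost with cyclic loess, with median scaling and without untreated replicate 2 or GFP replicate 2 (adjusted p = 0.179, 0.0888, 0.0931 and 0.0771).

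ESRRG and PPARGC1A, not above background in untreated cells, were at least 2.25-fold and at least 2.61-fold higher in GFP, while ESRRA did not pass (0.22 ± 0.13, adjusted p = 0.171) and PPRC1 fell by 1.42 ± 0.11. The list had 2 of 5 genes higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.744). CAT rose by 2.04 ± 0.11 and SOD2 by 1.94 ± 0.12. The other lists that did not pass in GFP against untreated were mitochondrial biogenesis (2 of 16 higher, 9 lower, median -0.36, adjusted p = 0.0742, but lower at 0.0271 with no filter on dim probes), mitochondrial ribosomal proteins (18 of 76 higher, 7 lower, adjusted p = 0.457), pyruvate oxidation and citrate cycle (3 of 17 higher, 3 lower, adjusted p = 0.891), antioxidant genes (7 of 24 higher, 7 lower, adjusted p = 0.868), mesenchymal regulators (6 of 13 higher, 3 lower, adjusted p = 0.557) and epithelial genes (4 of 11 higher, 2 lower, adjusted p = 0.973). Nor did the pluripotency network (0 of 5 higher, 2 lower, adjusted p = 0.147), hypoxia response (4 of 13 higher, 7 lower, 0.474), chromatin regulators (10 of 25 higher, 7 lower, 0.973), cholesterol synthesis (3 of 14 higher, 4 lower, 0.891), immune markers (1 of 4 higher, 2 lower, 0.877), neuronal markers (1 of 3 higher, 0 lower, 0.856) or reference genes (3 of 8 higher, 3 lower, 0.877). Of the delivered factors (adjusted p = 0.877), KLF4 rose in GFP against untreated by 0.98 ± 0.12 (adjusted p = 1.32e-05), while its other detected probe did not pass (0.29 ± 0.13, adjusted p = 0.0802). MYC fell by 0.39 ± 0.12 (adjusted p = 0.0113), a call lost without untreated replicate 2 (0.0637), without GFP replicate 2 (0.0631) and with median scaling (0.055), and the other MYC probe did not pass (-0.28 ± 0.12, 0.0582). In all, 15 of 30 lists passed, 8 higher and 7 lower in GFP, and 2 with an estimated correlation. The median, mean and test differed in sign for the epithelial, citrate cycle, chromatin, hypoxia, cholesterol, immune, neuronal and reference lists.

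**Figure D3:**
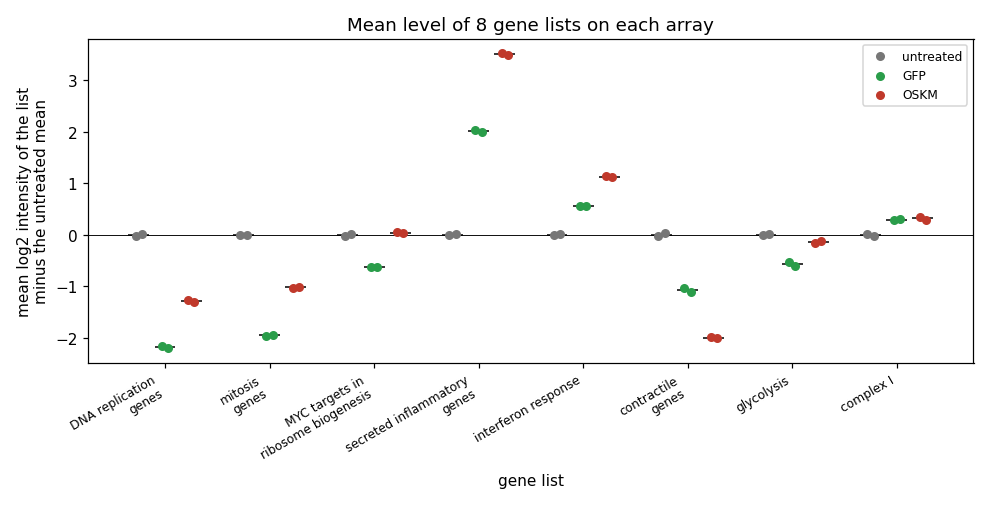
Mean log2 intensity of 8 gene lists on each of the 6 arrays, minus the mean of the untreated arrays (vertical axis), by group, with a line at the mean of 2 arrays. The inflammatory list lay highest on the OSKM arrays, and the DNA replication and mitosis lists lay lowest on the GFP arrays.

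The comparison of OSKM with untreated cells holds infection and the 4 factors together, with any other difference between these cultures. Inflammatory genes were far higher and contractile and cell division genes lower in OSKM than in untreated cells. KYNU was at least 80.8-fold higher (its other detected probe rose by 5.48 ± 0.11) and H19 at least 43.2-fold. The cytokine IL1B, detected on 1 of the 2 untreated arrays, rose by 6.63 ± 0.14, and CXCL8 by 6.47 ± 0.12. CORIN, a serine protease that processes natriuretic peptide, was at least 22.7-fold lower, ANO1 at least 29-fold lower and the smooth muscle myosin MYH11 at least 9.1-fold lower. In limma 5330 genes passed, 2683 higher and 2647 lower in OSKM, and 1186 differed at least 2-fold, 647 higher and 539 lower (666 in all with normexp and an offset of 50, 787 among genes detected on all 6 arrays). Further rises were in PTGS2 (5.96 ± 0.13), CXCL1 (5.90 ± 0.15, detected on 1 of the 2 untreated arrays), CD24 (at least 30.4-fold) and PDK4 (at least 36-fold). The other detected CD24 probe rose by 1.43 ± 0.11. Further falls were in CNN1 (at least 11.6-fold lower), ADAMTS8 (at least 10.8-fold lower), ALKAL1 (-3.62 ± 0.13, detected on 1 of the 2 OSKM arrays), LBH (-3.42 ± 0.12) and GPER1 (at least 6.65-fold lower, with 1 of its 2 other detected probes at -3.33 ± 0.12 and the other not past, -0.13 ± 0.11, adjusted p = 0.344).

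Secreted inflammatory genes rose in 18 of 18 against untreated and contractile genes fell in 12 of 12, also when adjusted over the list alone, with medians of 3.44 and -1.85. DNA replication genes fell in 24 of 25 (median -1.37) and mitosis genes in 26 of 28 (median -1.09), with the same counts when adjusted over the list alone. Interferon response genes rose in 19 of 25 and fell in 1 (20 and 1 when adjusted over the list alone). This list test was added after the data had been seen: 15 of 30 lists passed, 11 higher and 4 lower in OSKM, with the median, mean and test of the hypoxia list differing in sign. The 5 lists just named kept their calls with an estimated correlation, at an adjusted p of 0.0395 for inflammatory, DNA replication and mitosis genes, 0.0437 for contractile genes and 0.0498 for interferon genes. ESRRA rose by 1.05 ± 0.13, NOX4 by 1.47 ± 0.13, OGDH by 1.00 ± 0.12, ATP5MC1 by 0.99 ± 0.12 and IDH3A by 0.75 ± 0.14, and PPARGC1A was at least 1.72-fold higher. The other detected NOX4 probe rose by 0.75 ± 0.12. ESRRG passed (5.36 ± 0.03 in OSKM against 5.03 ± 0.13, not above background, in untreated cells, adjusted p = 0.0317), with no fold, since the bound is under 1. That call was lost without untreated replicate 1, OSKM replicate 1 or OSKM replicate 2 (adjusted p = 0.161, 0.126 and 0.0829), and in 5 other settings (adjusted p from 0.0636 with the authors' values to 0.152 with normexp and an offset of 50).

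Several mitochondrial lists were higher in OSKM than in untreated cells by small medians, but not mitochondrial biogenesis (6 of 16 higher, 3 lower, median 0.04, adjusted p = 0.788) or pyruvate oxidation and citrate cycle (7 of 17 higher, 2 lower, adjusted p = 0.237). Complex I rose in 16 of 33 (adjusted p = 0.0031; adjusted p = 0.0929 with an estimated correlation). Complexes II to IV with cytochrome c rose in 15 of 22 and fell in 1 (adjusted p = 0.00311; adjusted p = 0.0964 with an estimated correlation). These counts were the same when adjusted over the list alone. ATP synthase rose in 9 of 16 and fell in 1, also when adjusted over the list alone (adjusted p = 0.0305; adjusted p = 0.16 with an estimated correlation), but not with median scaling or cyclic loess (adjusted p = 0.129 and 0.0718). Fatty acid oxidation rose in 10 of 18 (11 when adjusted over the list alone; adjusted p = 0.00227; adjusted p = 0.0929 with an estimated correlation). These lists were higher in GFP than in untreated cells as well. For complex I the medians were 0.26 in OSKM and 0.23 in GFP, and for complexes II to IV 0.38 and 0.33. For ATP synthase they were 0.37 and 0.38, and for fatty acid oxidation 0.43 and 0.65. Mitochondrial ribosomal proteins differed more, with 0.21 in OSKM and 0.06 in GFP. Mitochondrial ribosomal proteins rose in 26 of 76 and fell in 1 (25 and 1 when adjusted over the list alone; adjusted p = 0.00277; adjusted p = 0.0873 with an estimated correlation). Cytosolic ribosomal proteins rose in 24 of 69 and fell in 2 (20 and 2 when adjusted over the list alone; adjusted p = 0.00277; adjusted p = 0.0873 with an estimated correlation), but not with median scaling or cyclic loess (adjusted p = 0.101 and 0.0708). The p53 targets were higher in 13 of 20 and lower in 1 (adjusted p = 0.000175; adjusted p = 0.0873 with an estimated correlation). Amino acid and unfolded protein stress genes were higher in 3 of 18 and lower in 13 (adjusted p = 0.00068; adjusted p = 0.0883 with an estimated correlation). The delivered factors were higher in 3 of 3 (adjusted p = 0.00311; adjusted p = 0.111 with an estimated correlation), but KLF4 rose here (0.75 ± 0.12) no more than in GFP cells (0.98 ± 0.12), which did not receive it. Nor did each probe rise: the other KLF4 probe did not pass (0.28 ± 0.13, adjusted p = 0.0957), and the other MYC probe fell by 1.71 ± 0.12 (adjusted p = 2.04e-07). Counts of these last lists were the same when adjusted over the list alone. The delivered factors lost their call with the probes of a gene averaged (adjusted p = 0.225), where MYC fell against untreated cells (-0.33, adjusted p = 0.0204). Other lists that did not pass in OSKM against untreated were the pluripotency network (adjusted p = 0.174, but higher at 0.0446 with median scaling), epithelial genes (0.193), immune markers (0.237), cholesterol synthesis (0.251), hypoxia response (0.323), glycolysis (0.377), matrix and surface genes (0.459), antioxidant genes (0.459), chromatin regulators (0.503), estrogen-related receptors and coregulators (0.692), reference genes (0.721), mesenchymal regulators (0.733) and MYC targets (0.76).

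Against the mean of both controls, 4004 genes passed in OSKM, 1975 higher and 2029 lower, and 538 differed at least 2-fold, 390 higher and 148 lower. That 2-fold count fell to 260 with normexp and an offset of 50, 330 with no background correction, 340 with the authors' values and 294 among genes detected on all 6 arrays. The count with no fold limit (4004) was lower when either OSKM array was left out. At least 2-fold higher in OSKM against each control were 203 genes, and at least 2-fold lower were 34, where independent lists of these sizes would share 29.9 and 13.1. Simulated unchanged groups shared 0 in either direction, so array noise alone does not give these counts. Both comparisons hold the same OSKM culture, which raises the sharing, so independent lists are a low reference. With the arrays of each group averaged and the 2 control cultures taken as replicates, limma called 0 genes (lowest adjusted p = 0.854). In that fit 208 of 10552 genes (1.97%) had an unadjusted p under 0.05. It has 1 OSKM sample and 1 residual degree of freedom and takes the difference between GFP and untreated cells as its error, so a count near 0 was close to fixed by the design and says nothing about stability.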

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

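Of the tests in this part, the comparison of MYC with the spread between probes of other genes was planned before its result was seen, and the other tests were chosen only afterwards. Probes without a gene name stand outside the comparisons of genes. Among the 3188 such probes that were detected, 59 were at least 2-fold higher in OSKM than in GFP, the control, and 35 at least 2-fold lower, and 21.1% were called in either direction by limma.

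More genes differed between GFP and untreated cells (6058) than between OSKM and GFP cells (4202). The choice among background corrections and normalizations does not account for the order, which held in 6 of 6 other settings. Each of these brings the arrays to a common scale, so an error that they share is not excluded. Dimmer untreated arrays are a poor account too: among genes detected on all 6 arrays the 2-fold count was still 2.58 times higher in GFP against untreated (1213 against 470). That filter also drops genes detected in only some groups. It cut the OSKM against GFP count (from 743) by a larger share than the other (from 1657), so only the order is read and not the size of the ratio. Also open is whether infection or the growth state of a single culture lies behind the order. Mitosis genes differed by a median of -2.03 between 1 culture of each kind, so a difference in growth between these cultures cannot be told apart from an effect of infection.

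The detected probes of MYC moved in opposite directions in OSKM against GFP, by 1.45 and -1.43, a gap of 2.89. Ordinary spread between probes of a gene is a poor account of this, since 4 of 2644 genes (0.15%) had a gap as large, CD24, SLC25A24, MBP and MYC itself, and the median gap was 0.21. A candidate explanation is that the delivered MYC transcript lacks the region of the falling probe, which would then read the cell's own MYC. The gap of 2.89 fits this but cannot decide it, as probe positions are not given in the sources used here.

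Changes in OSKM against GFP ran opposite to those in GFP against untreated: 210 genes rose at least 2-fold in the former and fell at least 2-fold in the latter, where independent lists would share 39, and 163 did the reverse, where they would share 19.7. The correlation across genes was -0.492, and simulated unchanged groups that share the GFP arrays gave -0.497, so the correlation alone shows nothing. The covariance was -0.234 against -0.00863 in the simulation, and with the GFP arrays split between the comparisons the smaller of 2 values was still -0.224, which argues against noise shared through these arrays. The simulation holds no differences between groups, so it covers array noise only. Both comparisons also hold the GFP culture, with opposite sign. Cultures that merely differ from one another would thus give a negative covariance and more opposite calls than independent lists, so neither speaks for a cause. A GFP culture out of line with 2 alike cultures is not the whole account for DNA replication, mitosis and amino acid stress genes, since the other 2 cultures were not alike there. The medians of these lists differed by -1.37, -1.09 and -0.94 between OSKM and untreated cells, with 24 of 25, 26 of 28 and 13 of 18 genes lower. Spread between cultures was not measured, so an odd GFP culture beside ordinary differences between the other 2 is not excluded. The share of genes lower needed for this reading was set after the data were seen for all 3 lists. The other 3 lists called in opposite directions do not decide it, since their members went both ways there: glycolysis (median -0.15), matrix and surface genes (-0.12) and MYC targets (0.04). A partial return of OSKM cells toward the untreated state may be a biological reading for lists called in opposite directions. Contractile, secreted inflammatory and interferon genes instead moved further from untreated cells. Their medians were -0.83, 1.89 and 0.43 in GFP against untreated and -0.84, 1.39 and 0.36 in OSKM against GFP. With 1 culture per group an odd GFP culture stays open for genes outside the first 3 lists named, and as part of the cause within them.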

How the results depend on the processing

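The list test of OSKM against untreated, with its alternatives, was chosen only after the data were seen, and the others were planned. Of 220 counts recomputed under other settings, 203 stayed within 1.5 times the reported count and 17 did not. Of 2968 values of genes named in the text, 2926 kept direction and call, 30 lost the call, 8 gained it and 4 changed sign. Of 1791 values of lists, 1725 were counted as kept, 61 lost the call, 4 gained it and 1 changed sign. Changes of sign were counted only for lists called in the main fit. A list called in neither fit was counted as kept whatever the sign of its median. With an estimated correlation 0 lists passed in OSKM against GFP (13 with the preset one), 2 in GFP against untreated (15) and 5 in OSKM against untreated (15). That setting also brings the test down to 3 residual degrees of freedom. The correlations estimated for DNA replication and mitosis genes (-0.03 and -0.01) lay below the preset 0.01, so for these a closer correlation is not what raised the p. Counts of genes at least 2-fold apart depended on the background correction. With normexp and an offset of 50 they fell to 352 in OSKM against GFP (from 743), 666 against untreated (from 1186), 260 against both controls (from 538) and 965 in GFP against untreated (from 1657), and an offset of 1 raised them to 1094, 1627, 790 and 2107. A larger offset shrinks changes of dim probes by construction. OSKM against GFP and against both controls gave 455 and 330 with no background correction and 461 and 340 with the authors' values. Among genes detected on all 6 arrays, where fewer genes were tested, they gave 470 and 294, and OSKM against untreated 787. Culture means, with 1 residual degree of freedom, gave 0 and 0 genes against both controls in limma, with 208 at an unadjusted p under 0.05. The design alone brings these called counts close to 0. Leaving out 1 array, the lone array being assumed to vary like the other groups, gave 2978 to 4443 genes in OSKM against GFP, 4255 to 5077 against untreated, 2633 (without OSKM replicate 1) to 3995 against both controls and 4953 to 5904 in GFP against untreated. The 2-fold counts were then 743 to 775, 1186 to 1246, 532 to 545 and 1657 to 1736, and lists 12 to 13 in OSKM against GFP, 15 against untreated and 13 to 15 in GFP against untreated. The changes of sign counted were in 3 genes and 1 list. In OSKM against GFP, NDUFA2 and NES, both uncalled, ranged from -0.276 to 0.006 and from -0.03 to 0.04 when 1 array was left out, with NDUFA2 at 0.006 and NES at -0.014 without GFP replicate 2 and NES at -0.03 without OSKM replicate 2. In OSKM against untreated, MYC was -0.326 (adjusted p = 0.0204) as the mean of probes that move apart, against 1.06, and neuronal markers had a median of -0.003 with no filter on dim probes (adjusted p = 0.121), against 1.42, as that setting adds markers not above background. With the replicate number as a replicate block the counts were 4141 in OSKM against GFP, 5272 against untreated, 6010 in GFP against untreated and 3936 against both controls, and no call of a named gene or list changed. Differences between replicates 1 and 2 correlated at -0.02 to 0.05 between groups, so the numbers do not pair the arrays. A slide block was not run, as the files name no slides. Signal over background limits what can be said of genes near the floor, whose changes are given as bounds, or with no fold where neither group was above background.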

Other observations

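The groups of genes described here were fixed before the data were examined, and the list test of OSKM against untreated was chosen only after the data were seen. Chromatin regulators went both ways in OSKM against GFP, 3 of 25 higher and 8 lower (6 and 8 when adjusted over the list alone; camera adjusted p = 0.622). The remodeller CHD1 rose by 0.69 ± 0.12, the histone methyltransferase SETDB1 fell by 0.56 ± 0.12, and SMARCD1, a SWI/SNF subunit, fell by 0.60 ± 0.14. The SMARCD1 call was lost without GFP replicate 2 (adjusted p = 0.0620) or OSKM replicate 1 (0.0527). Hypoxia response genes also split, 3 of 13 higher and 4 lower (3 and 5 when adjusted over the list alone; adjusted p = 0.688), with NDRG1 at 1.27 ± 0.14 and the angiogenic factor VEGFA at -0.63 ± 0.16 (lost without GFP replicate 2, adjusted p = 0.0890, without OSKM replicate 2, 0.0588, or with no detection filter, 0.0615). Cholesterol synthesis genes rose in 4 of 14, also when adjusted over the list alone (adjusted p = 0.0802, but 0.0165 with no filter on dim probes), among them the sterol sensor INSIG1 (0.84 ± 0.14) and the reductase DHCR7 (0.76 ± 0.13).

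Markers of other cell types were mostly not above background. Of 9 neuronal markers with a probe, 3 were tested, and in OSKM against GFP 2 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.0718, but 0.00576 with median scaling). STMN2 was at least 23.8-fold higher and GAP43, a growth cone protein, at least 2.05-fold, while the tubulin TUBB3 fell by 0.52 ± 0.12. GAP43 was not above background in either control and was tested only because it was detected in OSKM. Against untreated cells 2 of the 3 rose, also when adjusted over the list alone (adjusted p = 0.0118; adjusted p = 0.145 with an estimated correlation, and 0.121 with no filter on dim probes, where the median turned to -0.003). Of 11 immune markers, 4 were tested and 1 rose, also when adjusted over the list alone (adjusted p = 0.548), CD14, a coreceptor for lipopolysaccharide (1.09 ± 0.12). Of 10 endothelial markers, TEK, the angiopoietin receptor, was the 1 tested, and it fell by 1.31 ± 0.11 in OSKM against GFP and rose by 1.70 ± 0.11 in GFP against untreated. Of 15 early germ layer genes with a probe, the 1 tested was the intermediate filament NES (9.04 ± 0.03 in GFP, 9.05 ± 0.05 in OSKM, limma adjusted p = 0.978). Among 8 reference genes, 3 rose in OSKM against GFP, also when adjusted over the list alone (adjusted p = 0.622), HPRT1 by 0.85 ± 0.13, PGK1 by 0.56 ± 0.13 and YWHAZ by 0.50 ± 0.12. The PGK1 call was lost without GFP replicate 2 (adjusted p = 0.0501) and was absent from its other detected probe (0.22 ± 0.12, 0.152), and the YWHAZ call without GFP replicate 1 (0.0635) or OSKM replicate 1 (0.0515).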
